A study of Homo sapiens with 6 samples.

How the data were processed

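RNA sequencing libraries from 3 human thyroid cancer cell lines were analysed from the authors' table of expression values, which holds 58884 gene identifiers and 6 libraries. Groups were taken from the sample titles: BHT-101 siControl, BHT-101 siCRABP2, FTC-133 siControl, FTC-133 siCRABP2, 8505C empty vector and 8505C CRABP2 vector, with 1 library in each. Per the labels' protocols, RNA was extracted with Trizol and libraries followed standard Illumina protocols. The values deposited by the authors are FPKM, scaled for exon length and library depth. FastQC, Trimmomatic 0.38 and featureCounts 2.0.0 on GRCh38 were used, per the submitters' processing notes. The aligner, the annotation release and whether counting used strand are not given in the sources used here, so reads from a gene and its antisense partner cannot be told apart, and reads of near-identical copies are uncertain.

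Depth was recovered from the values. FPKM multiplied by the GENCODE release 29 exon length fell on whole multiples of a single step per library, which gives the total of reads behind each column. For 74.9% of the 33848 genes above 0 the release 29 length gave whole reads, and with another length found by search 96.9% did, at a tolerance of 0.001 reads. The totals were 27958622 and 22340806 reads for BHT-101 with siControl and siCRABP2, 24823867 and 27187323 for FTC-133 with siControl and siCRABP2, and 22849556 and 22084110 for 8505C with the empty and the CRABP2 vector. Gene names came from GENCODE release 29 (58611 identifiers) and a table of gene names, which together named 58641. That release may not be the one the authors used. Positions are those of GENCODE release 29 on GRCh38. Recovered reads were used for read numbers of single genes, shares of reads, counts of genes with few reads and 95% exact (Clopper-Pearson) intervals of the ratio of 2 libraries, which cover counting error only and compare libraries, not conditions.

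Values were analysed as log2(FPKM + 1), so differences understate the change of low genes. Within a line, a gene was measured if FPKM was at least 1 in 1 or both of its 2 libraries, and called by size if the 2 libraries differed by at least 1 on this scale. With 1 library per group no test across genes was made within a line. Lists from different lines were compared with the overlap expected from independent lists, over genes measured in both lines. Over lines, limma 3.58.1 (R 4.3.3) with a variance trend and the cell line as a block was fitted to the 4 siRNA libraries (FPKM of at least 1 in 2 or more) and to all 6 (FPKM of at least 1 in 3 or more), with Benjamini-Hochberg adjustment at 0.05. The pairing of libraries comes from the cell line named in the labels. The 6-library fit set the lower CRABP2 arm (siCRABP2, empty vector) against the higher arm (siControl, CRABP2 vector). These fits have 1 and 2 residual degrees of freedom.

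Each of 26 gene lists (604 entries, 590 distinct genes, all matched to the table) was summarised in each line by the median difference of its measured members and its percentile among 10000 random lists of the same size, drawn from 20 bins of mean expression. The percentile describes these libraries. Over lines, lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation. The estimated form takes its degrees of freedom from the residuals of the fit. An adjustment over the members of a list alone was added outside the plan. It does not allow for the choice among 26 lists. The lists are integrin subunits, focal adhesion and AKT pathway, mesenchymal markers, epithelial markers, collagens and laminins, matrix proteases and plasminogen system, retinoid receptors and handling, retinoic acid-induced genes, PPAR targets, thyroid differentiation, stemness, drug efflux transporters, BCL2 family and apoptosis inhibitors, p53 targets, proliferation, interferon-stimulated genes, NF-kB and inflammatory cytokines, integrated stress and unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, YAP targets, MAPK feedback and immediate early genes, replication-dependent histones, mitochondrially encoded genes, cytosolic ribosomal proteins, and markers of other cell types.

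Genes were named by a fixed rule: CRABP2; in each line the 8 protein-coding genes with the largest rise and the 8 with the largest fall among those with FPKM of at least 5; up to 10 per direction shared by both knockdowns, and those running the other way in 8505C; up to 4 members of each list with the largest difference; all measured integrin subunits, PTK2 and the AKT genes; and the 5 per direction with the smallest p in each limma fit. Members of shared sets, leave-one-out calls and further list members such as MKI67, TOP2A, IL6, IL1A and IL1B were named after their values were seen. The groups, comparisons, tests, size rule, lists, naming rule and alternatives were set before the data were examined, except for those said here to have been added.

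Alternatives were a pseudocount of 0.1, no filter on low values, FPKM of at least 5, centring on the median change, quantile normalization, limma without the block or the trend, and leaving out each line from the 6-library fit. Added after the data were seen were overlaps of the knockdown lines with 8505C beyond the genes shared by both knockdowns, correlations across genes, counts over protein-coding genes only, counts of genes whose counting interval excludes no change, list medians after a quadratic fit on GC content and exon length had been removed, chromosome medians over genes with FPKM of at least 5 against 10000 random gene sets, as deposited and with that trend removed, and a fit for each of the 10 splits of the 6 libraries into 3 and 3. The methods were tested on simulated data. With 200 changed genes and an assumed dispersion of 0.02, the limma fit for the siRNA libraries recovered 90% of 2-fold and 100% of 4-fold changes with 47 false calls out of 13197 genes, and the 6-library fit recovered 98% and 100% with 16 false calls out of 11552. Against 200 changed genes, 47 false calls exceed what an adjusted p under 0.05 allows. Each simulated change had the same fold in every line. The recovered shares therefore do not carry over to responses that differ between lines, as for CRABP2 (-1.19 in BHT-101, -3.09 in FTC-133). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.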

Results

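Gene expression was measured by RNA sequencing in 6 libraries of human thyroid cancer cell lines, each made from total RNA of cultured cells. BHT-101 and 8505C are established anaplastic thyroid carcinoma lines, and FTC-133 is an established follicular thyroid carcinoma line. BHT-101 and FTC-133 received either a small interfering RNA against CRABP2 (siCRABP2) or a control siRNA (siControl), and 8505C received either a CRABP2 expression vector or the empty vector. Each of these conditions was represented by 1 library, so no difference within a line has a replicate check. Nothing in the sources used here says that cultures of the same line were grown separately. With the cell line as a block, p-values over the lines measure how far the difference varies between these lines, mixed with noise between these libraries. The read totals recovered from the FPKM values ran from 22084110 to 27958622 per library. CRABP2 encodes a cellular retinoic acid-binding protein that carries retinoic acid to its nuclear receptors. The series asked how lowering or raising it changes gene expression in these cells, and what is known of the study points to integrin, focal adhesion and AKT genes as a question of interest.

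CRABP2 itself (ENSG00000143320, GRCh38 chromosome 1, 156699606 to 156705816, minus strand, protein-coding) followed the labels in every line. In BHT-101 it was 27.3 FPKM (826 reads) in the siControl library and 11.4 FPKM (276 reads) in the siCRABP2 library, a difference of -1.19 on the log2(FPKM + 1) scale. In FTC-133 it was 8.94 FPKM (240 reads) with siControl and 0.17 FPKM (5 reads) with siCRABP2, a difference of -3.09. In 8505C it was 0.607 FPKM (15 reads) with the empty vector and 38.0 FPKM (909 reads) with the CRABP2 vector, a difference of 4.60. The 95% exact counting interval of the depth-scaled log2 read ratio ran from -1.46 to -1.06 in BHT-101, from -7.35 to -4.47 in FTC-133 and from 5.24 to 6.81 in 8505C. Such intervals cover counting error only, and reads without molecular tags are not independent draws. The knockdown therefore left more CRABP2 transcript in BHT-101 than the siControl library of FTC-133 held.

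**Figure D1:**
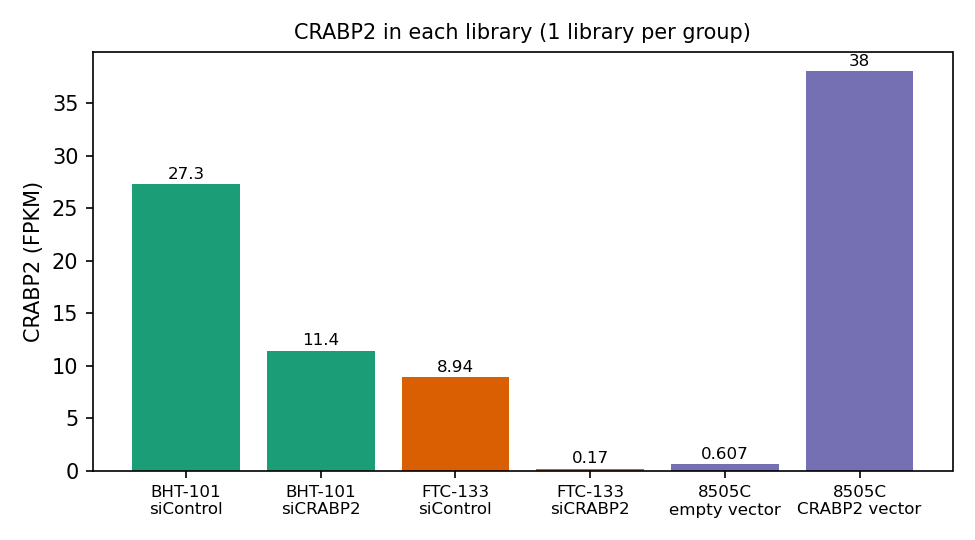
CRABP2 level in FPKM (vertical axis) in each of the 6 libraries, with bars coloured by cell line and the value printed above each bar. The siCRABP2 bars stand at 11.4 and 0.17 FPKM against 27.3 and 8.94 FPKM with siControl, and the CRABP2 vector bar stands at 38.0 FPKM against 0.607 FPKM with the empty vector.

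In BHT-101, IFI6, an interferon-induced mitochondrial protein, was 77.6 FPKM with siControl and 322 FPKM with siCRABP2 (2.04 on the log2 scale). The neutrophil chemokine CXCL5 went from 6.04 to 21.6 FPKM (1.68), the acute-phase protein SAA1 from 28.3 to 76.4 FPKM (1.40), the iron-binding lipocalin LCN2 from 11.2 to 28.9 FPKM (1.30) and the interferon-induced IFI27 from 64.4 to 154 FPKM (1.24). The antimicrobial peptide DEFB1 and the hepatokine FGL1 each differed by 1.42, and the vitamin B12-binding protein TCN1 by 1.39. SAA1 has a near-identical neighbour, SAA2, so its reads are uncertain.

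In the same BHT-101 comparison, 28 of 29 measured interferon-stimulated genes were above 0, with a median difference of 0.59, higher than every one of 10000 random lists of matched expression. MX1, an antiviral GTPase, went from 3.70 to 7.88 FPKM and OAS2, which senses double-stranded RNA, from 4.64 to 10.9 FPKM. NF-kB targets and inflammatory cytokines had a median of 0.15 with 13 of 19 measured members above 0, above the random range of -0.08 to 0.11. Cholesterol synthesis genes lay the other way, with 22 of 24 below 0 and a median of -0.23. Among them SQLE, which makes squalene epoxide, went from 163.5 to 111 FPKM and INSIG1, a sterol sensor, from 56.3 to 40.9 FPKM. The 18 measured p53 targets had a median of -0.12 and the 21 MAPK feedback and immediate early genes a median of -0.08, both below their random ranges. All 13 mitochondrially encoded protein genes were below 0, with a median of -0.26. All genes of the mitochondrial genome together, RNA genes included, held 5.43% of reads with siControl and 4.73% with siCRABP2.

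By the rule of size, a difference of at least 2-fold on log2(FPKM + 1), 71 genes were higher and 65 lower in BHT-101 with siCRABP2, out of 12055 measured. Most rested on few reads: 52 of the higher and 51 of the lower genes had under 20 reads in both libraries, and the counting interval excluded no change for 29 and 25. Only 16 of the higher and 3 of the lower genes were protein-coding. The 3 lower genes were CRABP2, the matrix proteoglycan BGN (7.07 to 2.81 FPKM, -1.08) and the tight junction protein CLDN2 (8.67 to 3.79 FPKM, -1.01). The next largest negative differences were under 2-fold, with the transcription factor MSC at -0.81, the collagen receptor MRC2 at -0.76, FOS and the monooxygenase-like MOXD1 at -0.72 each, and the sugar phosphate transporter SLC37A2 at -0.71. The difference between the 2 BHT-101 libraries correlated with gene GC content (Pearson -0.382 across genes, which are not independent replicates).

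FTC-133 cells were then compared between siCRABP2 and siControl. CSF2, which encodes the growth factor GM-CSF, was 0.204 FPKM with siControl and 37.9 FPKM with siCRABP2 (5.01 on the log2 scale). The neutrophil chemokine CXCL8 went from 2.72 to 90.3 FPKM (4.62), the pattern recognition protein PTX3 from 3.87 to 64.7 FPKM (3.75), the stress cytokine GDF15 from 6.04 to 76.2 FPKM (3.46), CXCL2 from 2.48 to 35.7 FPKM (3.40) and CXCL1 from 20.6 to 216 FPKM (3.33). SAA1 differed by 3.32 and the Notch target HES4 by 3.04. CXCL1 and CXCL2 are close paralogs, so reads between them are uncertain. Lower in the siCRABP2 library were the differentiation inhibitors ID2 (14.9 to 1.01 FPKM, -2.98) and ID3 (77.4 to 12.7 FPKM, -2.52), the immediate early genes EGR1 (27.7 to 3.31 FPKM, -2.74) and FOS (-2.55), the cancer-testis gene SSX1 (-2.72), the chemokine CXCL12 (-2.25) and the transcription factor LHX1 (-1.96).

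In FTC-133 all 19 measured NF-kB targets and inflammatory cytokines were above 0, 14 of them at least 2-fold, and the median was 1.56. The interleukins IL6 (1.91 to 11.8 FPKM), IL1B (0.520 to 9.01 FPKM) and IL1A (0.531 to 6.48 FPKM) were among them. Interferon-stimulated genes had a median of 1.095, with 30 of 32 above 0 and 18 at least 2-fold higher. OASL differed by 1.86, HERC5, a ligase for the ubiquitin-like ISG15, by 1.80 and MX1 by 1.77. Integrated stress and unfolded protein response genes had a median of 0.74 (20 of 23 above 0, 7 at least 2-fold), led by the transcription factors DDIT3 (8.69 to 50.9 FPKM, 2.42) and ATF3 (2.11), the glutathione-degrading CHAC1 (2.03) and the pseudokinase TRIB3 (1.96). Cholesterol synthesis genes had a median of 0.38 (15 of 22 above 0), with the sterol oxidase MSMO1 at 1.05 and SQLE at 0.87. Proliferation genes lay below 0 in 30 of 32 cases, with a median of -0.50. The proliferation marker MKI67 went from 16.7 to 9.74 FPKM and the topoisomerase TOP2A from 93.7 to 60.5 FPKM. Mitochondrially encoded genes were below 0 in 13 of 13 cases (median -0.62), and the whole mitochondrial genome held 3.69% and 2.88% of reads. Each of these medians lay outside the 95% range of its random lists.

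In FTC-133, 303 genes were at least 2-fold higher and 302 at least 2-fold lower with siCRABP2, out of 12832 measured. Of these, 184 and 145 were protein-coding, and the counting interval excluded no change for 267 and 244. These counts describe 2 libraries, and no test across genes was made.

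8505C cells with the CRABP2 vector were compared with cells holding the empty vector. KNL1, a kinetochore scaffold protein, was 0.290 FPKM with the empty vector and 8.31 FPKM with the CRABP2 vector (2.85 on the log2 scale). KISS1, the precursor of kisspeptin, went from 6.87 to 54.3 FPKM (2.81), the potassium channel KCNK1 from 2.03 to 17.8 FPKM (2.63), the protein kinase A inhibitor PKIB from 1.66 to 14.9 FPKM (2.58), the tetraspanin-like TM4SF19 from 0.530 to 7.58 FPKM (2.49) and the lysosomal protease CTSL from 364.7 to 2026 FPKM (2.47). Lower with the CRABP2 vector were the matrix proteins ABI3BP (16.2 to 1.80 FPKM, -2.62) and FBLN1 (19.6 to 3.35 FPKM, -2.25), the elastase inhibitor PI3 (-2.19), the growth factor binding protein IGFBP1 (106 to 26.1 FPKM, -1.98), the reticulum autophagy receptor RETREG1 (-1.97), FRMD8 (-1.97) and the protease CTSS (-1.91). GAGE12J (0.405 to 6.95 FPKM) and VCX3B (12.4 to 0.462 FPKM, -3.19) belong to families of near-identical copies, and TM4SF19 overlaps an antisense gene, so their reads are uncertain.

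Proliferation genes were above 0 in 25 of 25 measured cases in 8505C, with a median of 0.69 and 5 members at least 2-fold higher, from low levels in both libraries. The mitotic kinase CDK1 was 0.724 FPKM with the empty vector and 5.31 FPKM with the CRABP2 vector, and the anaphase activator CDC20 was 1.33 and 4.68 FPKM. The median FPKM of the 32 proliferation genes was 0.712 in the empty vector library and 2.06 in the CRABP2 vector library, against 11 in BHT-101 and 25.5 in FTC-133 with siControl. NF-kB targets and inflammatory cytokines were below 0 in 19 of 21 cases (median -0.70, 6 at least 2-fold lower). Among them CXCL8 went from 1136 to 493.5 FPKM (-1.20), CXCL1 from 333 to 122 FPKM (-1.44) and IL1B from 355 to 163 FPKM (-1.12). Collagens and laminins were below 0 in 16 of 18 cases (median -0.52), with COL6A2 at -1.28 and the fibrillar collagen COL3A1 at -1.05. Mitochondrially encoded genes were below 0 in 13 of 13 cases (median -0.90), although MT-CO3 turned to 0.11 under quantile normalization. The whole mitochondrial genome held 2.68% of reads with the empty vector and 1.61% with the CRABP2 vector. Interferon-stimulated genes were above 0 in 10 of 20 cases, with a median of 0.007, at percentile 48.3 of the random lists.

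In 8505C, 217 genes were at least 2-fold higher and 218 at least 2-fold lower with the CRABP2 vector, out of 11731 measured. Of these, 130 and 121 were protein-coding, and the counting interval excluded no change for 176 and 162. Genes of chromosome 18 shifted together between the 2 libraries. The median over its 83 genes with FPKM of at least 5 was 0.43, against a 95% range of -0.06 to 0.12 for random gene sets of that size, and 94% of them lay above the median of all genes. Chromosome 21 had a median of 0.29 and chromosome 17 a median of -0.16, and 17 of the 23 chromosomes lay outside their random ranges. In BHT-101 14 chromosomes and in FTC-133 3 chromosomes did so, with medians no larger than 0.08 upward in either line. After removal of the trend on GC content and length the numbers were 19 in 8505C, 6 in BHT-101 and 3 in FTC-133. The lowest chromosome median was -0.06 in BHT-101 and -0.14 in FTC-133. Whether the 8505C vector cultures were selected clones or pools is not given in the sources used here, which bears on every difference in this line. This look at chromosomes was chosen after the values were seen.

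**Figure D2:**
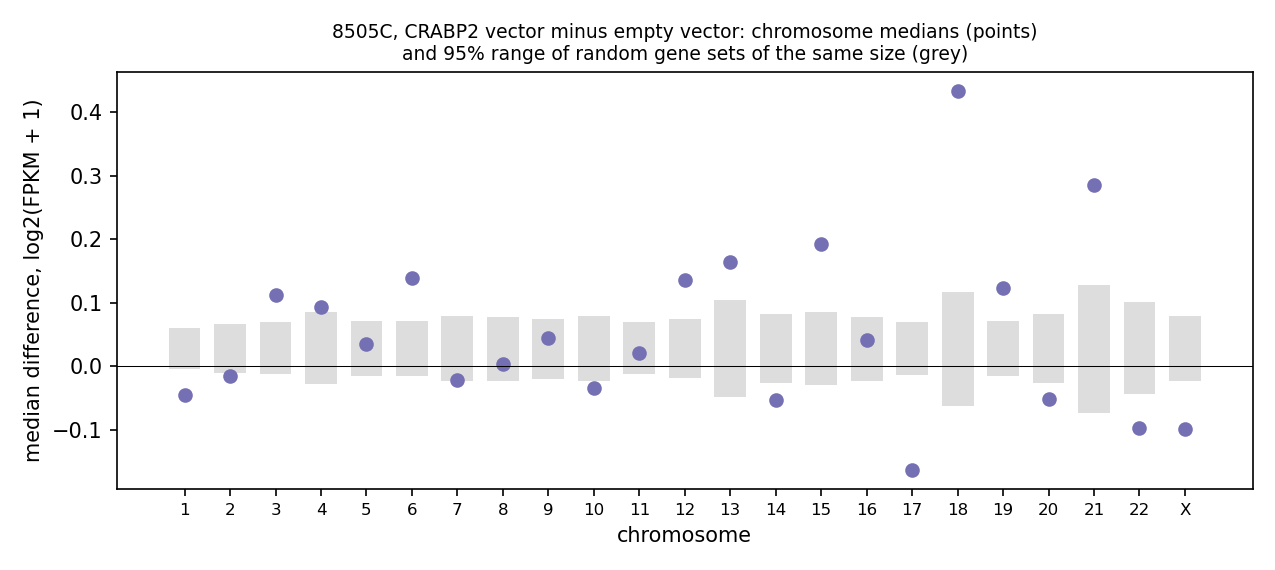
Median difference on log2(FPKM + 1) between the CRABP2 vector and empty vector libraries of 8505C (vertical axis) for the genes of each chromosome (horizontal axis), with points for the medians and grey bars for the 95% range of random gene sets of the same size. Chromosome 18 stands highest at 0.43 and chromosome 17 lowest at -0.16.

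The 2 knockdown lines were set side by side to ask which genes answered to siCRABP2 in both. IFI6, IFI27, the antiviral membrane protein IFITM1, OAS2, CXCL5, SAA1 and LCN2 were at least 2-fold higher with siCRABP2 in both BHT-101 and FTC-133. These 7 genes compare with 0.174 genes expected from independent lists. CXCL5 differed by 1.68 and 2.85, IFITM1 by 1.01 and 2.05, and OAS2 by 1.08 and 1.30 in BHT-101 and FTC-133. CRABP2 was the only protein-coding gene at least 2-fold lower in both. Over all biotypes 9 genes were shared upward and 10 downward, with 0.489 and 0.395 expected. Genes going opposite ways exceeded expectation too, with 5 higher in BHT-101 and lower in FTC-133 (0.395 expected) and 4 lower in BHT-101 and higher in FTC-133 (0.489 expected), none of them protein-coding, so the excess over all biotypes is not specific to a shared direction. The remaining shared genes were short RNA genes and transcripts of low read number, apart from FP236383.3, a long noncoding RNA gene at 23.3 and 5.09 FPKM in BHT-101.

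Tested over both knockdown lines, the interferon-stimulated genes were higher as a list with a preset correlation only. Over the 26 lists, with limma and the cell line as a block, 31 of 31 tested members were higher with siCRABP2 (median 0.85), and camera with a preset correlation gave an adjusted p = 2.2e-34, against an adjusted p = 0.966 (p = 0.149) with an estimated correlation. Adjusted over the list alone, 24 of the 31 passed, against 0 over all genes tested. The adjustment over a list alone was not planned and ignores the choice among the 26 lists, so it describes the list and calls no gene. NF-kB targets and inflammatory cytokines (19 of 20 up, 3 passing when adjusted over the list alone) had an adjusted p = 2.4e-12 by camera, and the stress response genes (18 of 22 up, 0 passing when adjusted over the list alone) an adjusted p = 7.8e-06, although in BHT-101 alone 10 of 22 measured members were above 0 (median -0.02) and FTC-133 carried the difference. With an estimated correlation both had an adjusted p = 0.966. For NF-kB targets most of the difference came from FTC-133 as well. Their median was 1.56 there (14 of 19 at least 2-fold higher) against 0.15 in BHT-101 (1 of 19). Proliferation genes (3 of 32 up) and mitochondrially encoded genes (0 of 13 up) were lower as lists, each with 0 members passing when adjusted over the list alone, with adjusted p = 6.9e-06 and 1.5e-07 by camera and an adjusted p = 0.966 for both with an estimated correlation. For proliferation genes FTC-133 carried this too, since in BHT-101 15 were above and 16 below 0, with a median of -0.02 inside its random range. None of the list calls held with an estimated correlation. That form rested on 1 residual degree of freedom in this fit and could hardly pass any list, so this outcome does not weigh against the lists.

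No single gene passed in the limma fit over the 4 siRNA libraries at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 314 higher and 225 lower genes out of 12953, and the smallest adjusted p was 0.25. IFI6 had a log2 difference of 1.74 (SE 0.19, higher in 2 of 2 lines, limma adjusted p = 0.338), CXCL5 of 2.27 (SE 0.28, adjusted p = 0.355) and LCN2 of 1.46 (SE 0.18, adjusted p = 0.355). Taking the 5 smallest p per direction, the others were IFI27 and the short RNA gene RNA5SP243 upward, and FP236383.3, AC067863.2, MIR6804, SNORD72 and MIR4479 downward.

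**Figure D3:**
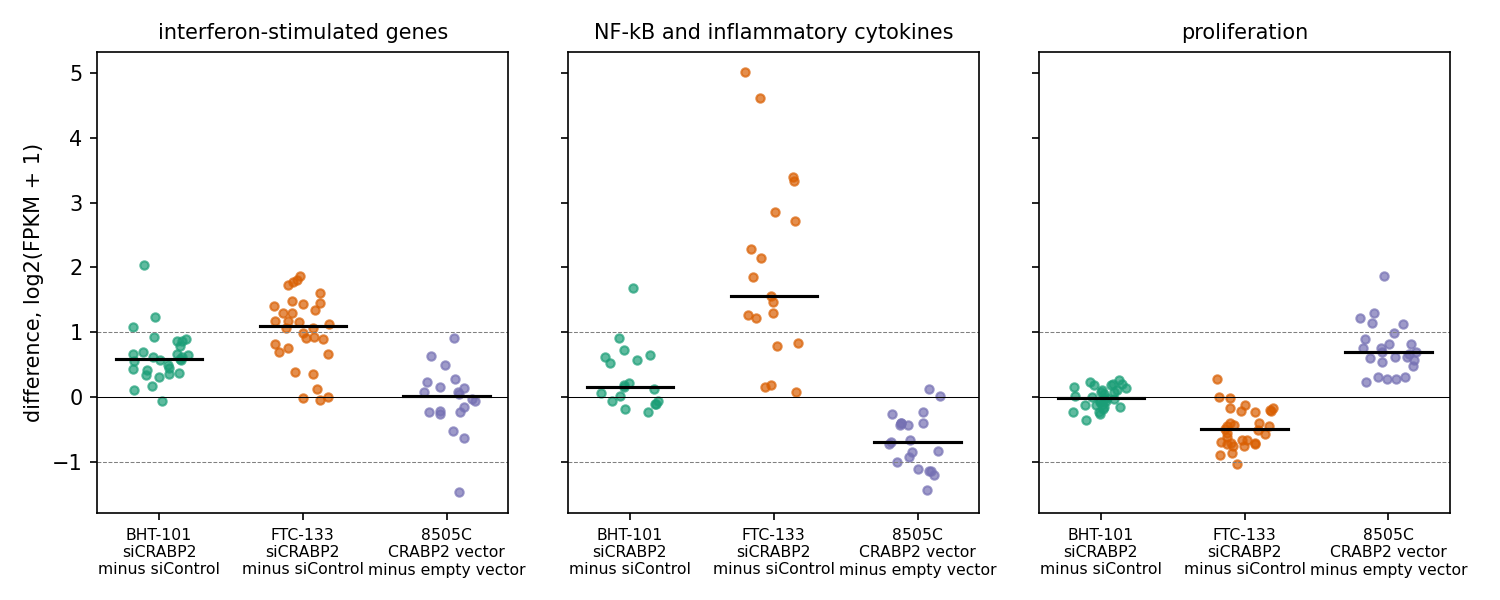
Difference between treated and control library on log2(FPKM + 1) (vertical axis) for each measured member of 3 gene lists in each cell line (points), with the list median as a black line and dashed lines at 2-fold. Interferon-stimulated genes have medians of 0.59 in BHT-101 and 1.095 in FTC-133 against 0.007 in 8505C, while NF-kB targets stand at 1.56 in FTC-133 and -0.70 in 8505C.

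All 3 lines were then combined, with the siCRABP2 and empty vector libraries as the lower CRABP2 arm and the siControl and CRABP2 vector libraries as the higher arm. The complement protease C1R was higher in the lower arm of every line, from 32.2 to 75.1 FPKM in BHT-101 and from 1.63 to 3.45 FPKM in FTC-133 with siCRABP2, and at 11.8 FPKM with the empty vector against 4.69 FPKM with the CRABP2 vector in 8505C. The growth factor binding protein IGFBP3 and the antiviral tetherin BST2 ran the same way, with limma log2 differences of 0.75 (SE 0.14) and 1.05 (SE 0.19). The DNA primase subunit PRIM1 ran with CRABP2, at -0.95 (SE 0.20), as did CRABP2 itself at -2.96 (SE 0.54). None of these passed: the limma adjusted p was 0.794 for C1R and 0.999 for the other 4, each with 3 of 3 lines in its direction. The remaining genes among the 5 smallest p per direction were WFDC21P, RF00569, SNORD14E, MT-TF and MIR3153, all RNA genes or pseudogenes.

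In that fit 0 genes passed at an adjusted p under 0.05 out of 11628 tested, and 193 were higher and 179 lower in the lower arm at an unadjusted p under 0.05. Leaving out FTC-133 gave 6 higher and 4 lower genes by limma, with C1R (adjusted p = 0.0296) and C1S (adjusted p = 0.041) the protein-coding ones beside MT-TQ, MT-TK, RF00569 and RF00015. The 4 lower genes were MIRLET7I, SNORD14E, SNORD99 and MIR6859-1. Leaving out BHT-101 gave CRABP2 alone, with a log2 difference of -3.84 and a limma adjusted p = 0.0138. Interferon-stimulated genes (29 of 29 up, 7 passing when adjusted over the list alone), NF-kB targets (22 of 23 up, 8 passing) and stress response genes (19 of 22 up, 0 passing) were higher as lists in the lower arm, with camera adjusted p = 1.3e-23, 1.5e-19 and 8.6e-08, against an adjusted p = 0.937 for each with an estimated correlation. The line-by-line medians differ from this: 8505C showed no shift of interferon-stimulated genes (0.007, 10 of 20 above 0), and BHT-101 none of stress response genes (-0.02, 10 of 22 above 0). Proliferation genes (0 of 31 up, 0 passing when adjusted over the list alone) were lower as a list, with camera adjusted p = 6.8e-18, carried by FTC-133 and 8505C and not by BHT-101 (median -0.02). With an estimated correlation its adjusted p = 0.937. That form rested on 2 residual degrees of freedom in this fit, so it could hardly pass a list here either.

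Protein-coding genes at least 2-fold higher in FTC-133 with siCRABP2 and at least 2-fold lower in 8505C with the CRABP2 vector numbered 12, against 1.32 expected from independent lists. They were BST2, C15orf48, CD55, CXCL1, CXCL8, IL1A, IL1B, IL6, NOTCH3, PANX2, SLC7A5 and TNFRSF9, several of them inflammatory mediators. The reverse set held 5 genes against 0.858 expected, namely APLN, CRABP2, the WNT inhibitor DKK1, ID3 and PRIM1. The same 2 lines also shared 8 genes higher in both (1.38 expected) and 2 lower in both (0.821 expected), so the excess is not specific to the opposite sense. BHT-101 and 8505C shared C1R and its partner protease C1S in this opposite sense. No protein-coding gene other than CRABP2 was at least 2-fold changed the same way in both knockdowns and at least 2-fold the other way in 8505C.

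Integrin subunits, the cell surface receptors for matrix, had list medians of 0.02 in BHT-101, -0.08 in FTC-133 and -0.09 in 8505C, all inside the random range. Among single subunits, ITGB8 went from 6.55 to 2.42 FPKM in FTC-133 (-1.14), and in 8505C ITGAV went from 33.1 to 13.2 FPKM (-1.26) and ITGB3 from 6.60 to 1.83 FPKM (-1.42). No other measured subunit reached 2-fold on the log2(FPKM + 1) scale, which shrinks low values. By the ratio of FPKM, ITGB4 in FTC-133 (1.87 to 0.734 FPKM, fold 2.54) and ITGAX in 8505C (162 to 47 reads, fold 3.33) were also lower by more than 2-fold. Over both knockdown lines the limma log2 difference was 0.43 for ITGB3 (SE 0.18, adjusted p = 0.869). For ITGAV it was 0.02 (SE 0.17, adjusted p = 0.991). ITGB1, the most abundant subunit, differed by 0.17, -0.05 and -0.20 in BHT-101, FTC-133 and 8505C. PTK2, the gene of focal adhesion kinase, differed by 0.13, 0.27 and 0.06, and AKT1 by 0.02, -0.19 and -0.02. The focal adhesion and AKT pathway list had medians of -0.02, -0.17 and -0.03, inside the random range in each line, and its largest member difference was FERMT1, an integrin activator, at 1.33 in 8505C. Neither list passed camera in either fit, and transcript levels say nothing of kinase phosphorylation.

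Retinoic acid-induced genes had medians of 0.07 in BHT-101, -0.35 in FTC-133 and 0.02 in 8505C. In FTC-133 13 of 14 were below 0, including ZNF703 (22.7 to 8.25 FPKM) and the chemerin gene RARRES2 (34.3 to 13.1 FPKM), and the median lay below the random range of -0.26 to 0.20. Retinoid receptors and handling genes had medians of 0.04, -0.18 and -0.19, within the random range, while the retinaldehyde-oxidizing ALDH1A1 went from 0.123 to 4.82 FPKM in 8505C (2.37) and the retinol carrier RBP4 from 38 reads to 1 (-1.05). PPAR targets had medians of 0.06, -0.05 and -0.30, the last below the random range, with CPT1A at -1.20 in 8505C. Mesenchymal markers had medians of -0.02, 0.10 and 0.13, with periostin (POSTN) at 1.76 in 8505C and tenascin C (TNC) at -1.15 in FTC-133. Epithelial markers had medians of 0.04, 0.23 and 0.68, the last over only 6 measured genes and 0.035 when no filter was applied, with the desmosome protein DSP at 1.26 in 8505C. Collagens and laminins stood at -0.07 in BHT-101 and -0.30 in FTC-133, where COL5A1 went from 94.5 to 36.3 FPKM (-1.36) and the laminin chain LAMB3 from 3.51 to 9.77 FPKM (1.26), and the FTC-133 median came to -0.10, inside the random range, once the trend on GC content and length was removed. Matrix proteases and plasminogen system genes had medians of -0.08, 0.43 and -0.21, the FTC-133 value above and the 8505C value below the random range, with the urokinase receptor PLAUR at 1.31 and collagenase MMP1 at 2.00 in FTC-133.

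Drug efflux transporters had medians of -0.02, -0.49 and -0.44 in BHT-101, FTC-133 and 8505C, with 8 of 8 measured members below 0 in FTC-133, where the median lay below its random range as deposited and after removal of the trend on GC content and length (-0.40). Stemness genes stood at 0.01, -0.28 and 0.12, with SOX9 at -1.47 in FTC-133 and HMGA2 at 1.28 in 8505C. Thyroid differentiation genes stood at 0.06, -0.17 and -0.31 over 6, 6 and 3 measured genes. BCL2 family genes and apoptosis inhibitors stood at 0.02, 0.13 and 0.24, with the apoptosis inhibitor BCL2A1 at 1.53 and the death effectors BBC3 at 1.49 and PMAIP1 at 1.29 in FTC-133. p53 targets stood at 0.15 in FTC-133, where the cell cycle inhibitor CDKN1A went from 9.39 to 32.8 FPKM (1.70), and at -0.19 in 8505C. Hypoxia and glycolysis genes stood at 0.001, 0.06 and 0.17, with NDRG1 at 2.06 in FTC-133, and YAP targets at -0.01, 0.18 and 0.10, with tissue factor (F3) at 1.77 in FTC-133. MAPK feedback genes stood at 0.12 in FTC-133 and 0.08 in 8505C, where the AP-1 component FOSL1 went from 46.5 to 202 FPKM (2.10). Replication-dependent histones stood at 0.13, -0.28 and 0.33, cytosolic ribosomal proteins at -0.04, 0.15 and 0.27 (the BHT-101 value below and the 8505C value above the random range, also after that removal), and stress response genes at -0.02 in BHT-101 and -0.19 in 8505C, the last below its random range. Cholesterol synthesis genes stood at 0.04 in 8505C. Markers of other cell types (leukocyte, endothelial, fibroblast) stood at 0.02, -0.81 and -0.06, over 5, 2 and 2 measured genes, the pair in FTC-133 being LUM and ACTA2, below the random range. In 8505C the medians of drug efflux, BCL2 family, p53 and histone genes lay outside their random ranges as deposited and inside them after removal of the trend on GC content and length. The same removal took other medians outside: stemness (-0.31), p53 (0.23), YAP (0.22) and histone genes (-0.34) in FTC-133, and hypoxia genes (0.21) in 8505C.

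**Figure D4:**
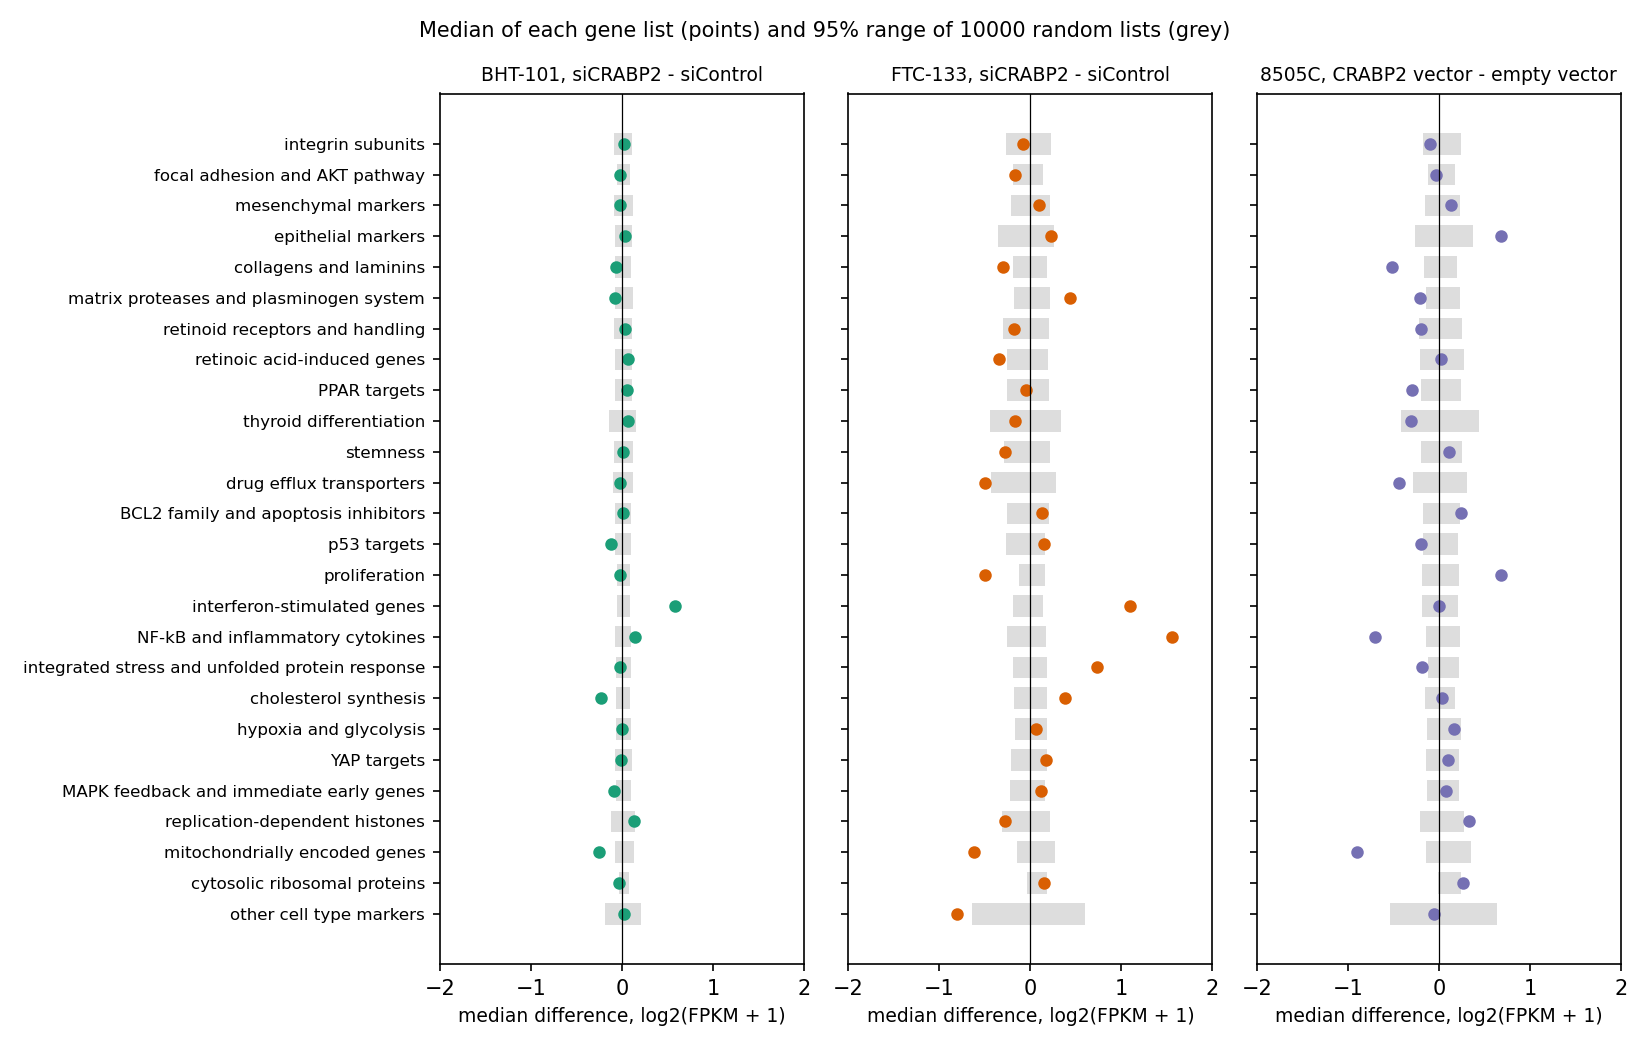
Median difference between treated and control library on log2(FPKM + 1) (horizontal axis) for each of the 26 gene lists (vertical axis) in the 3 cell lines (panels), with points for the medians and grey bars for the 95% range of 10000 random lists of matched expression. Interferon-stimulated genes lie right of the grey bar in both knockdown lines, at 0.59 and 1.095, and mitochondrially encoded genes lie left of it in all 3 lines, at -0.26, -0.62 and -0.90.

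Across all measured genes the treated-minus-control differences correlated weakly and positively between every pair of lines. Pearson's coefficient was 0.147 (Spearman 0.150) between BHT-101 and FTC-133 over 10658 genes, 0.0831 (0.127) between BHT-101 and 8505C, and 0.0785 (0.128) between FTC-133 and 8505C. The sign was positive with 8505C although CRABP2 was raised there and lowered in the other lines. These 3 coefficients are across genes, which are not independent replicates, and the lines share no control library.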

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

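The list medians in this part were planned, and the GC and length correction was chosen only after they had been seen. Cholesterol synthesis genes went opposite ways in the 2 knockdown lines. In BHT-101 22 of 24 were below 0 with siCRABP2, and in FTC-133 15 of 22 were above 0, so that the list medians (-0.23 and 0.38) differed by 0.604, with each outside its random range. SQLE differed by -0.55 in BHT-101 and 0.87 in FTC-133, INSIG1 by -0.45 and 0.85, IDI1, an isoprenoid isomerase, by -0.23 and 0.81, and MSMO1 by -0.43 and 1.05. After correction the medians were -0.23 and 0.36. The difference between the lines was not tested, since each line has 1 library per condition.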

How the results depend on the processing

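The alternatives restricted to protein-coding genes, restricted by the counting interval, or corrected for GC content and length were chosen only after the results were seen. No result took the opposite direction among those called. The counts of genes at least 2-fold different (higher and lower) were 71 and 65 in BHT-101, 303 and 302 in FTC-133, and 217 and 218 in 8505C. With a pseudocount of 0.1 they were 174 and 128, 561 and 717, and 478 and 417. With FPKM of at least 5 they were 21 and 13, 169 and 154, and 102 and 106, and over protein-coding genes only 16 and 3, 184 and 145, and 130 and 121, where fewer genes enter the count. For BHT-101, genes whose counting interval excludes no change numbered 29 and 25. Genes higher in both knockdown lines went from 9 to 21 with the pseudocount of 0.1. Genes lower in both went from 10 to 18 with that pseudocount, to 6 with FPKM of at least 5 and to 1 over protein-coding genes. The CRABP2 difference at a pseudocount of 0.1 was -5.06 in FTC-133 and 5.75 in 8505C, since a smaller pseudocount shrinks low values less. Leaving out each line from the 6-library limma fit gave 0 to 6 genes higher and 0 to 4 lower in the lower CRABP2 arm. The limma fit over the 4 siRNA libraries gave 0 genes under every alternative run, the fit without the block for the cell line included, and leaving out a line there leaves no residual degrees of freedom, so it was not run. No paired analysis by replicate number was possible because the labels give none.

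Among list medians, 529 of 543 alternatives moved the median by less than the distance from the centre of its random range to a bound, and 14 moved it further. Among named genes, 2331 of 2484 moved by no more than the distance from the centre of the counting interval to a bound, and 153 moved further. In 8505C the epithelial marker median was 0.68, and 0.035 with no filter on low values. For named genes at least 2-fold different, 0 of 768 alternatives changed sign and 10 came under 2-fold. The moved values with another sign were 3, all under quantile normalization: MT-CO3 in 8505C (0.11), RPL7 in BHT-101 (0.12) and RPL15 in FTC-133 (-0.08). Depth limits genes of few reads most, as with the 52 and 51 of the BHT-101 genes under 20 reads.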

Other observations

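The overlap of FTC-133 with 8505C was unplanned, and every test that weighs a pattern here was chosen only after that pattern was seen, the corrections for GC content and length and the share of chromosome 18 genes before their own outcome was known. Some genes ran the same way in FTC-133 with siCRABP2 and in 8505C with the CRABP2 vector, although CRABP2 went opposite ways. The protein-coding genes at least 2-fold higher in both were CTSL, the phosphatase DUSP5, KCNK1, the keratin KRT17, the sphingosine kinase SPHK1, the anticoagulant receptor THBD, TM4SF19 and TMEM158, 8 genes against 1.38 expected from independent lists. CTSL differed by 1.70 in FTC-133 and 2.47 in 8505C, with 0.54 in BHT-101, and DUSP5 by 2.02 and 1.02. Those lower in both were C1QL1 and the syndecan SDC3, 2 genes against 0.821 expected.

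Interferon-stimulated genes were higher with siCRABP2 in BHT-101 and FTC-133. A difference in GC content or length handling between libraries is argued against, since the BHT-101 median after correction was 0.524 and above its random range, as in FTC-133. A response that follows the CRABP2 level inversely in all 3 lines was not seen in 8505C, where the median was 0.007 and only 20 of the 32 genes were measured. Over all 32 genes the list was low there, with a median of 1.15 FPKM with the empty vector. With siControl that median was 7.19 FPKM in BHT-101 and 6.74 FPKM in FTC-133. Genes not measured in 8505C had little room for a fall. Among the 20 measured genes a fall could be seen, as for BST2 (-1.47), but 10 were above 0. Their median lay inside the random range of -0.182 to 0.209, so these genes showed no shared fall. With 1 library per group the 8505C value cannot exclude such a response. Innate sensing of the siRNA itself cannot be told apart from an effect of CRABP2 loss: IFNB1 and IFNL1, genes of interferons, had 28 reads over both siCRABP2 libraries and 2 over both siControl libraries, which either could give. Most of these reads were in FTC-133 (1 with siControl, 21 with siCRABP2), and BHT-101 had 1 and 7. A second siRNA sequence was not analysed here.

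Mitochondrially encoded genes were lower in the treated library of all 3 lines. A link to the CRABP2 level in a fixed direction is argued against by the 8505C median of -0.895, since CRABP2 went up there and down in the knockdowns. A GC or length trend is argued against by the corrected BHT-101 median of -0.349, the smallest in size of the 3 lines and still below its random range. RNA handling or a cell state that differs between treated and control cultures may underlie it and stays open, with 13 of 13 genes lower in every line, because treatment and culture coincide.

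Genes of chromosome 18 were higher in 8505C with the CRABP2 vector. A GC or length trend is argued against by the corrected median of 0.425, and a few strongly different genes by the 94% of genes above the median of all genes. A copy number difference between the 2 cultures is a candidate explanation, with a long-arm median of 0.491 and a short-arm median of 0.42. It stays open, since no DNA was analysed here and the sources used here do not say whether the cultures were clones or pools. The test also asked that chromosome 18 stay inside its random range in both siRNA lines. In BHT-101 its median of 0.061 lay just above the upper bound (0.060), and it was 0.003 after correction. As 14 of 23 chromosomes lay outside their ranges in that line as deposited, this small excess does not decide the question for 8505C. 

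The count of genes over all 6 libraries was 0, and the highest of the other splits into 3 and 3 gave 2 by limma. With a real count of 0 the comparison carries no information, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 372 genes. Of the other splits that part every cell line, control against treated libraries gave 697 and the remaining ones 346 and 331. In the 6 splits that keep 2 lines whole, the block for the cell line leaves the contrast to the 2 libraries of the parted line, so their counts (2, 2, 0, 0, 0 and 0 adjusted; 1868, 1115 and 45 unadjusted, each from a pair of splits) describe single lines and are no measure for the real split.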
